A study of Mus musculus with 7 samples.

How the data were processed

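Per the labels' protocols, CD8+ T cells of gBT-I mouse spleens were enriched with magnetic beads against CD8, stained for CD44, CD122, CD8 and CD4, and sorted at over 95% purity, and small RNA libraries were made with the Illumina TruSeq kit. The authors deposited a table of estimated counts for each mature miRNA arm and precursor, with fractional values. The aligner and the counter were not given in the sources used here, and the genome build was mm10 per the submitters' processing notes. The table had 2128 lines with 1978 mature names, of which 85 stood on more than 1 line, and 1234 precursors. After summing per mature name, 84.0% of nonzero values lay within 0.02 of a whole number, and sums were rounded, which moved a value by at most 0.5.

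Libraries were grouped by the titles into adult VM, adult TN, neonatal VM and neonatal TN, and all 7 were used. The 288 miRNAs with at least 10 CPM in at least 2 libraries were tested, which is 15.8 to 32.8 counts at library totals of 1577031 to 3278451. Counts were scaled by TMM factors and tested in edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood test and robust dispersions, with Benjamini-Hochberg adjustment at 0.05 within each comparison. Age and subset averages came from an additive model with 4 residual degrees of freedom, and the 5 other comparisons from a cell means model with 3. CPM values are scaled by the TMM factors, and SE are those of the fitted log2 fold change. The design, lists and naming rule were fixed before the data were examined.

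Named miRNAs were, among those past the test with a mean of at least 50 CPM, the 12 largest increases and 12 largest decreases for the 2 averages, the 5 and 5 largest within an age or subset, and the 10 smallest adjusted p for the interaction; the 10 most abundant and examples from the lists were added. There were 15 lists: let-7, miR-17~92, miR-29, miR-130 and miR-301, miR-181, miR-15/16, miR-23/27/24 and miR-30 families or clusters, T cell activation, resting T cell, Dlk1-Dio3 locus, H19 and Igf2, and erythroid, myeloid and progenitor, and stromal and muscle markers. The 11 lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry beside it. The estimated correlation was not always positive. For the miR-130 and miR-301 family with age in VM it was -0.282, yet camera's unadjusted p rose from 7.34e-04 to 0.0405. A higher p under that setting therefore cannot be laid to correlation between members alone. The erythroid list had 2 tested members, miR-486a-5p and miR-486b-5p, and the stromal list 2, miR-143-3p and miR-10b-5p, so neither had a set test. Coordinates and host genes came from GENCODE M21 and RefSeq names on GRCm38.

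Alternatives were RLE, library total and upper quartile scaling, library sizes without the 5 most abundant miRNAs, no filter, a 100 CPM filter, filterByExpr, DESeq2 1.42.0, limma voom, non-robust dispersions, the replicate number as a block, an averaged contrast, only the libraries compared, and each library left out; the largest precursor value per name and a GC offset were chosen after seeing the data. The method was tested on simulated data with 100 changed miRNAs. For log2 changes of 1 and 2, it recovered 76.1% and 97.9% for age over both subsets (263 miRNAs), 60.9% and 97.8% for subset over both ages (260), 27.1% and 82.2% for age in TN (267), 47.8% and 90.0% for age in VM (270), 33.3% and 89.8% for subset in adult cells (275), 11.6% and 64.6% for subset in neonatal cells (261) and 6.52% and 57.4% for the interaction (267). False calls made up 5.66% of the calls for age in TN, 6.25% for subset in adult cells, 6.25% for the interaction and at most 4.29% for the other comparisons. The simulation gave the lone neonatal TN library the same dispersions as the other libraries, so it cannot check whether that library varies like them. It also gave adult VM the same dispersions, although its replicates lay further apart. The SD of the log2 difference between replicates was 0.72 in adult VM, 0.48 in adult TN and 0.43 in neonatal VM. The simulated recovery and false calls may therefore not hold for comparisons that use adult VM. Figures were drawn with matplotlib 3.10.9. Reads, isomiRs and target genes were not analysed here.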

Results

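MicroRNAs (miRNAs) were counted in CD8+ T cells sorted from the spleen of neonatal and adult gBT-I mice, whose T cells carry a transgenic receptor. CD44hi CD122hi cells, known in the field as virtual memory (VM) cells, carry memory markers although they have met no antigen, and CD44lo CD122lo cells are the true naive (TN) cells. The groups held 2 adult VM, 2 adult TN, 2 neonatal VM and 1 neonatal TN library, so values of neonatal TN cells have no SD. Totals were 2714219 and 3278451 counts for adult VM, 2056813 and 2990544 for adult TN, 1577031 and 3006539 for neonatal VM and 2982273 for neonatal TN. The labels do not say whether replicates came from separate animals, so the p-values measure the spread between these libraries, which may be technical. The question addressed was which miRNAs differ with age and with subset in naive CD8+ T cells.

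Of 1978 mature miRNAs listed, 878 had a count and 288 were tested. The 10 most abundant, by mean CPM over all 7 libraries, were miR-150-5p, miR-92a-3p, miR-142a-5p, miR-181a-5p, miR-21a-5p, miR-26a-5p, miR-16-5p, let-7f-5p, miR-27b-3p and miR-191-5p. The order differed by group. Of these 10, miR-181a-5p took the largest share in the neonatal TN library (18.5%) and miR-92a-3p in neonatal VM (12.2 ± 1.26%, SD, n = 2). MiR-150-5p, a miRNA abundant in mature lymphocytes that targets Myb, took 33.5 ± 0.746% of the counts in adult TN (SD, n = 2), 19.7 ± 1.88% in adult VM (n = 2) and 9.20 ± 1.05% in neonatal VM (n = 2). In the neonatal TN library it took 6.71% (95% Wilson interval 6.68 to 6.74%, which covers counting error only, since reads without molecular identifiers are not independent molecules). MiR-92a-3p, from the miR-17~92 cluster, stood at 178498 ± 22429.7 CPM (scaled by TMM factors) in adult TN, 130573 ± 13403 in adult VM, 125219 in neonatal TN and 95394 ± 9382 in neonatal VM. The first principal component of log2 CPM held 61.7% of the variance and separated neonatal from adult libraries. The second held 25.5% and separated VM from TN libraries. Across the tested miRNAs, which are not independent replicates, Pearson's r between replicates was 0.981 for adult VM, 0.991 for adult TN and 0.992 for neonatal VM. The adult VM replicates differed by over 2-fold at 35 of 288 miRNAs, against 11 in adult TN and 11 in neonatal VM. MiR-423-5p, chosen after its values were seen, differed most between them, at 6334 CPM in replicate 1 and 194 CPM in replicate 2.

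**Figure D1:**
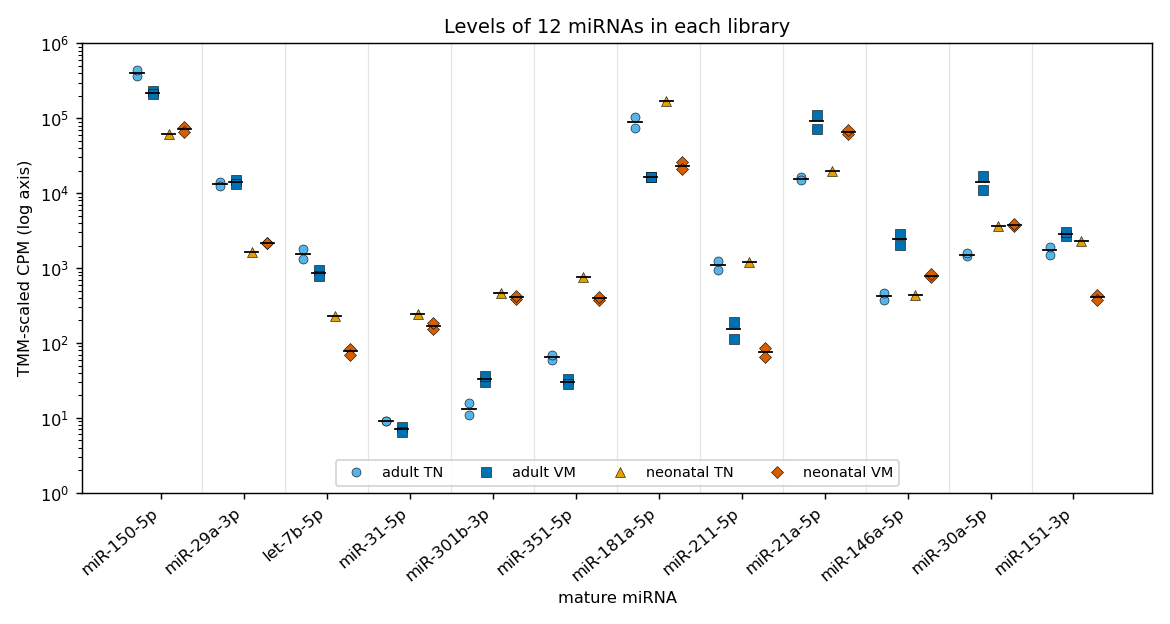
Points are TMM-scaled CPM per library on a log axis for 12 miRNAs, coloured by group, and horizontal lines are group means. MiR-31-5p, miR-301b-3p and miR-351-5p lie higher in neonatal libraries, and miR-150-5p, miR-29a-3p and let-7b-5p lower.

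The comparison of neonatal with adult cells, taken over both subsets, asked which miRNAs change with age. MiR-31-5p, which is induced by T cell receptor signals, was 24.9-fold higher in neonatal cells, at 241 CPM in neonatal TN and 170.1 ± 23.0 in neonatal VM (mean ± SD, n = 2), against 9.09 ± 0.132 in adult TN and 7.11 ± 0.764 in adult VM (n = 2 each; log2 fold change 4.64, SE 0.23, edgeR adjusted p = 1.96e-06). MiR-301b-3p rose 18.6-fold, from 13.3 ± 3.57 CPM in adult TN and 32.9 ± 4.36 in adult VM to 466 in neonatal TN and 406 ± 24.5 in neonatal VM (log2 fold change 4.22, SE 0.33, edgeR adjusted p = 3.39e-05). In the other direction, miR-29a-3p, which represses T-bet and interferon gamma, was 7.15-fold lower in neonatal cells, at 1644 CPM in neonatal TN and 2148 ± 22.3 in neonatal VM against 13219 ± 1229.7 in adult TN and 14216 ± 1296 in adult VM (log2 fold change -2.84, SE 0.18, edgeR adjusted p = 9.01e-06). Let-7b-5p, of the family whose maturation LIN28 blocks, was 9.13-fold lower (log2 fold change -3.19, SE 0.24, edgeR adjusted p = 3.06e-05). MiR-150-5p was 4.04-fold lower, from 400665 ± 49188 CPM in adult TN and 218782 ± 15212 in adult VM to 62296 in neonatal TN and 72063 ± 7845 in neonatal VM (log2 fold change -2.01, SE 0.25, edgeR adjusted p = 2.60e-04).

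In all, 155 of 288 miRNAs passed the test with age, 76 higher and 79 lower in neonatal cells (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p at most 0.05). The other named increases, as log2 fold changes, were miR-298-5p (3.99), miR-351-5p (3.64), miR-301a-3p (3.39), miR-148a-3p (2.64), miR-744-5p (2.44), miR-181a-2-3p (2.17), miR-296-3p (2.13), miR-181d-5p (2.09), miR-322-5p (2.06) and miR-5099 (1.87). The other named decreases were miR-3535 (-2.63), miR-467d-5p (-2.60), miR-669a-3p (-2.34), let-7c-5p (-2.29), miR-101a-3p (-2.14), miR-29c-3p (-2.01), miR-378d (-1.99), miR-361-3p (-1.92) and miR-139-5p (-1.90). On GRCm38 (mm10), Mir31 lies in an exon of the lincRNA AL805899.1 (chromosome 4, 88910557 to 88910662). Mir301b (chromosome 16, 17124400 to 17124496) and Mir130b (chromosome 16, 17124061 to 17124142) each lie in an intron of 2610318N02Rik. Mir351 (chromosome X, 53053255 to 53053353) and Mir322 (chromosome X, 53054255 to 53054349) lie about a kilobase apart, within no host gene of their strand. Mirlet7b lies in an exon of Lncppara (chromosome 15, 85707319 to 85707403). Mir29a (chromosome 6, 31062660 to 31062747) and Mir150 (chromosome 7, 45121757 to 45121821) lie within no host gene of their strand.

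By family, all 3 measured miR-29 members fell with neonatal age (camera adjusted p = 0.0082; adjusted p = 0.425 with an estimated correlation). All 4 members of the miR-130 and miR-301 family rose (camera adjusted p = 0.0082; adjusted p = 0.425 with an estimated correlation), with miR-130a-3p at 2.35 (2.16 ± 3.05 CPM in adult TN, 14.1 ± 13.1 in adult VM, 42.7 in neonatal TN and 34.8 ± 4.41 in neonatal VM) and miR-130b-3p at 1.75. In the let-7 family, 5 of 9 members fell, among them let-7g-5p at -1.19, 4 did not pass, and the family as a set did not pass (camera adjusted p = 0.0661), though it did under library totals (0.0461) and without adult VM replicate 2 (0.0374) or adult TN replicate 1 (0.0429). Scaled by library totals alone, 3 let-7 members were called lower and 1 higher, and none of the 5 turned sign. Let-7 members differ by few bases, so the split of reads between them is uncertain. All 4 miR-181 members, a family that tunes T cell receptor sensitivity in thymocytes, rose (miR-181a-5p 0.69, miR-181b-5p 1.46, miR-181c-5p 0.90, miR-181d-5p 2.09), with a set adjusted p of 0.0603, and of 0.041 with RLE factors, 0.0198 under library totals and 0.0162 and 0.0376 without adult and neonatal VM replicate 2. Of the 12 measured T cell activation miRNAs, 4 rose, among them miR-31-5p, miR-210-3p (2.92) and miR-146b-5p (1.77), 2 fell, including miR-155-5p (-1.36), and 6 did not pass (camera adjusted p = 0.466). Among 9 resting T cell miRNAs, 3 fell, miR-150-5p, miR-101a-3p and miR-139-5p, and 6 did not pass (camera adjusted p = 0.12); the median of the list was -0.33, and 0.12 under library totals.

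The remaining lists did not pass as sets with age. The miR-17~92 clusters had 3 of 13 members higher, including miR-18b-5p (3.03) and miR-363-3p (1.19), and miR-92a-3p lower at -0.48 (camera adjusted p = 0.647). The miR-15/16 family had 1 higher and 2 lower of 6 (camera adjusted p = 0.953), the miR-23/27/24 clusters 1 higher of 6 (camera adjusted p = 0.953) and the miR-30 family 1 lower of 5 (camera adjusted p = 0.719). Adjusted over the list alone, the age counts were 4 higher and 3 lower for T cell activation and 1 higher and 1 lower for miR-15/16, and the same as above for the other 9 tested lists. Among markers of other cells, miR-126a-5p (2.17) and miR-126a-3p (1.28) were higher and miR-10a-5p (-1.52) lower (myeloid and progenitor list, camera adjusted p = 0.719). The stromal marker miR-143-3p was at 47.6 ± 18.1 CPM in neonatal libraries (n = 3) and 13.9 ± 9.45 in adult libraries (n = 4). The erythroid miR-451a stood at 6.16 ± 3.39 CPM in neonatal (n = 3) and 2.46 ± 0.455 in adult libraries (n = 4). No member of the Dlk1-Dio3 locus list (57 members, highest miR-127-3p at 11.2 CPM) or of the H19 and Igf2 list (highest 0.623 CPM) was tested. Scaled by library totals alone, 119 miRNAs were higher and 53 lower with age, and the median of all tested miRNAs moved by 0.45 on the log2 scale, so directions of small changes are relative to the centre that TMM sets.

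**Figure D2:**
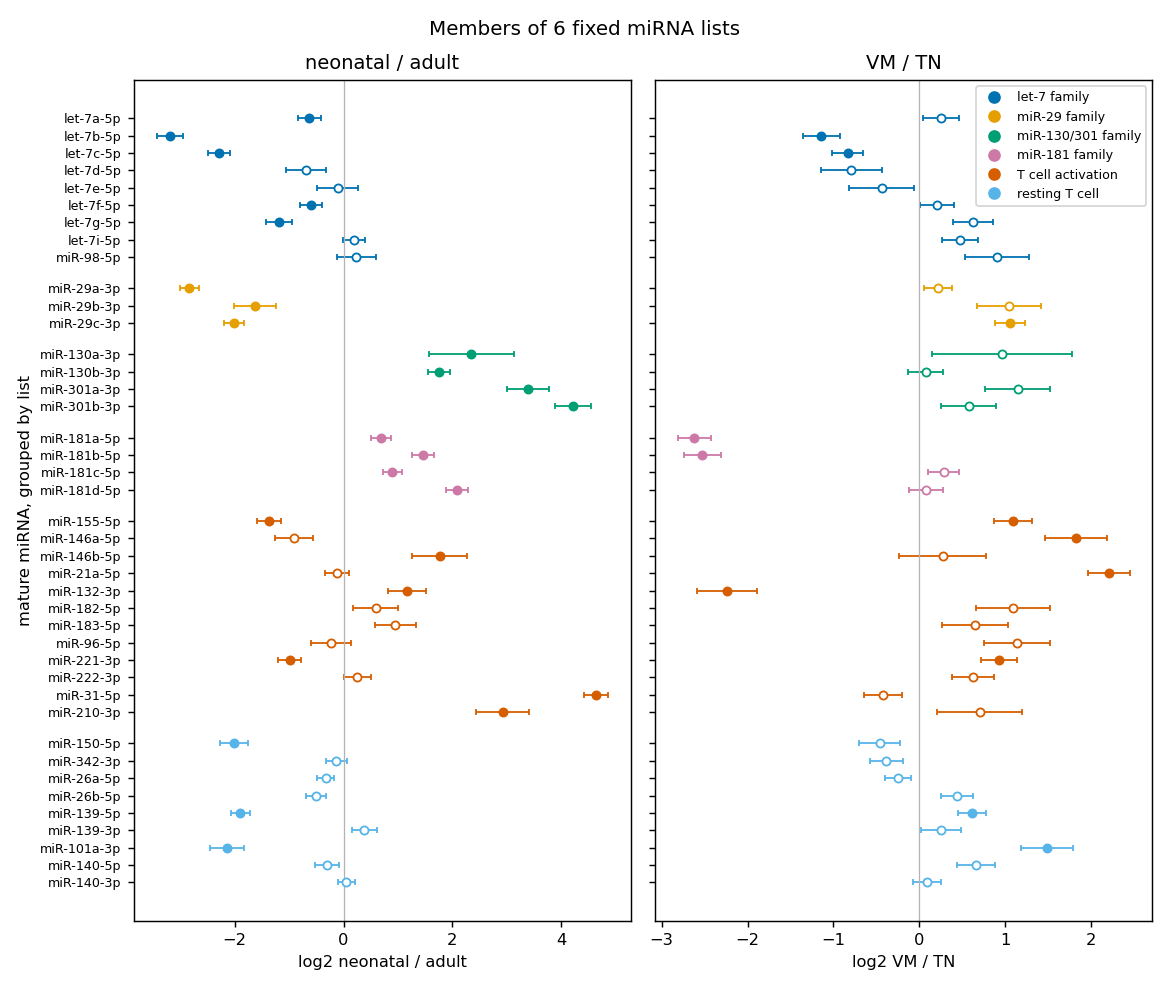
Points are log2 fold changes of the members of 6 lists for neonatal over adult cells and for VM over TN cells, bars are SE, and filled points passed the edgeR test. The miR-29 members lie below 0 and the miR-130 and miR-301 members above 0 with age, and miR-181a-5p and miR-181b-5p lie below 0 by subset.

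The comparison of VM with TN cells, taken over both ages, asked which miRNAs mark the subsets. MiR-21a-5p, which rises on T cell activation, was 4.62-fold higher in VM cells, at 90969 ± 27445 CPM in adult VM and 66188 ± 5144 in neonatal VM (n = 2 each) against 15586 ± 1092 in adult TN (n = 2) and 20023 in neonatal TN (log2 fold change 2.21, SE 0.24, edgeR adjusted p = 4.10e-04). Its other arm, miR-21a-3p, rose too (log2 fold change 2.29, SE 0.24, edgeR adjusted p = 3.22e-04). MiR-181a-5p was 6.14-fold lower in VM cells, at 16429 ± 1.67 CPM in adult VM and 23343 ± 3619 in neonatal VM against 89129 ± 21658 in adult TN and 171918 in neonatal TN (log2 fold change -2.62, SE 0.19, edgeR adjusted p = 3.22e-05). MiR-211-5p was 9.92-fold lower, at 154 ± 56.2 and 75.1 ± 14.1 CPM in adult and neonatal VM against 1085 ± 199.9 and 1199 in adult and neonatal TN (log2 fold change -3.31, SE 0.31, edgeR adjusted p = 1.70e-04). MiR-146a-5p, which restrains NF-kB signalling, rose (log2 fold change 1.82, SE 0.36, edgeR adjusted p = 0.0127), as did miR-155-5p, processed from the activation-induced Bic transcript (log2 fold change 1.09, SE 0.22, edgeR adjusted p = 0.0135). The rise of miR-146a-5p differed by age, with log2 fold changes of 2.52 in adult and 0.86 in neonatal cells.

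By subset, 71 of 288 miRNAs passed the edgeR test, 31 higher and 40 lower in VM cells. The other named increases, as log2 fold changes, were miR-340-5p (1.90), miR-101a-3p (1.48), miR-340-3p (1.08), miR-200a-3p (1.07), miR-203-3p (1.05), miR-29c-3p (1.05), miR-142a-5p (0.98) and miR-221-3p (0.93). The other named decreases were miR-181a-2-3p (-3.69), miR-181b-5p (-2.52), miR-181a-1-3p (-2.49), miR-669a-5p (-1.51), miR-99b-5p (-1.37), miR-467d-5p (-1.30), miR-125a-5p (-1.16), miR-467a-5p (-1.15), let-7b-5p (-1.14) and miR-150-3p (-1.09). Mir21a lies in an exon of Vmp1 (chromosome 11, 86584067 to 86584158), Mir211 in an intron of Trpm1 (chromosome 7, 64205806 to 64205911), Mir181a-1 in an intron of Gm4258 (chromosome 1, 137966460 to 137966540) and Mir340 in an intron of Rnf130 (chromosome 11, 50069702 to 50069799). Mir181a-2 (chromosome 2, 38852735 to 38852810) and Mir146 (chromosome 11, 43374397 to 43374461) lie within no host gene of their strand, and Mir155 lies in an exon of Mir155hg (chromosome 16, 84714140 to 84714204). Mir467d lies in an intron of Sfmbt2 (chromosome 2, 10507630 to 10507714), among near-identical copies whose reads could be split between them, so values of miR-467 and miR-669 members are uncertain.

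Of the 4 miR-181 members, miR-181a-5p and miR-181b-5p fell in VM cells, while miR-181c-5p (0.29, edgeR adjusted p = 0.26) and miR-181d-5p (0.08, edgeR adjusted p = 0.814) did not pass. The family passed as a set (camera adjusted p = 0.017; adjusted p = 0.52 with an estimated correlation). Of the 12 T cell activation miRNAs, 4 rose, miR-21a-5p, miR-146a-5p, miR-155-5p and miR-221-3p, miR-132-3p fell (-2.24), and 7 did not pass (camera adjusted p = 0.0417; adjusted p = 0.52 with an estimated correlation). Adjusted over the list alone, 5 higher and 1 lower passed in the activation list and 0 higher and 2 lower in the miR-181 family. No other tested list passed as a set by subset, and none of the 7 tested markers of other cells passed. Under library totals 59 miRNAs were higher and 27 lower, with a median shift of 0.16, and under upper quartile factors 58 were higher and 25 lower, with a median shift of 0.14. The count was 42 with the replicate number as a block. It was 35 without adult VM replicate 1, 25 and 18 without adult TN replicates 1 and 2, and 47 and 20 without neonatal VM replicates 1 and 2. Without the neonatal TN library the fit compared adult VM with adult TN cells alone, and it called 111. Without adult TN replicates 1 and 2 the activation list had camera adjusted p = 0.128 and 0.115 (0.0554 under library totals and 0.066 with the block). Without the neonatal TN library, so between adult cells alone, the miR-181 family had camera adjusted p = 0.142. With either adult TN library left out, 12 of the 24 named miRNAs did not pass, miR-146a-5p (edgeR adjusted p = 0.07 and 0.0627), miR-101a-3p, miR-155-5p, miR-340-3p, miR-200a-3p, miR-203-3p, miR-142a-5p, miR-221-3p, miR-669a-5p, miR-99b-5p, miR-125a-5p and miR-150-3p. Of these, 5 also did not pass in some setting with all libraries. MiR-340-3p failed with RLE factors, the 100 CPM filter, the block, the largest precursor value and the GC offset. MiR-125a-5p failed with library totals, upper quartile factors, the block and the GC offset. MiR-99b-5p and miR-150-3p failed with upper quartile factors and the GC offset, and miR-142a-5p with the block.

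Within TN cells, where the 1 neonatal library was set against 2 adult ones, the question was how age alters true naive cells. MiR-301b-3p (log2 fold change 5.11, SE 0.29, edgeR adjusted p = 2.00e-07), miR-31-5p (4.72), miR-301a-3p (4.38), miR-298-5p (3.82) and miR-351-5p (3.58) rose most in neonatal TN cells among miRNAs with a mean of at least 50 CPM, as log2 fold changes. MiR-29a-3p (log2 fold change -3.01, SE 0.25, edgeR adjusted p = 2.88e-06), miR-669a-3p (-2.96), let-7b-5p (-2.78), miR-150-5p (-2.69) and miR-467d-5p (-2.59) fell most at that level. All 4 miR-130 and miR-301 members rose (camera adjusted p = 8.90e-05; adjusted p = 0.211 with an estimated correlation), as did all 4 miR-181 members (camera adjusted p = 0.0246; adjusted p = 0.319 with an estimated correlation). In the miR-29 family 2 of 3 fell (camera adjusted p = 0.0246; adjusted p = 0.319 with an estimated correlation), and among T cell activation miRNAs 5 of 12 rose and 2 fell (camera adjusted p = 0.0246; adjusted p = 0.319 with an estimated correlation). Adjusted over the list alone, these counts were 4 higher and 0 lower for miR-130 and miR-301, 4 higher and 0 lower for miR-181, 0 higher and 2 lower for miR-29 and 5 higher and 2 lower for activation. Among markers of other cells, miR-143-3p (3.3) and miR-126a-5p (3.46) were higher in neonatal TN cells. In all, 138 miRNAs passed the edgeR test, 76 higher and 62 lower, against 106 and 38 under library totals (median shift 0.36) and 56 and 79 under upper quartile factors (median shift -0.31). Without adult TN replicates 1 and 2, 86 and 83 miRNAs passed, and without adult TN replicate 1 the activation, miR-181 and miR-29 lists had adjusted p = 0.062, 0.062 and 0.052, while without adult VM replicate 2 the activation list had 0.064.

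Within VM cells, the same question was asked of 2 neonatal and 2 adult libraries. MiR-31-5p (log2 fold change 4.58, SE 0.30, edgeR adjusted p = 3.10e-07), miR-298-5p (4.11), miR-351-5p (3.69), miR-301b-3p (3.62) and miR-744-5p (2.84) rose most at that level. Let-7b-5p (log2 fold change -3.49, SE 0.24, edgeR adjusted p = 3.10e-07), miR-3535 (-3.15), miR-151-3p (-2.82), miR-151-5p (-2.74) and miR-29a-3p (-2.73) fell most at that level. In the miR-130 and miR-301 family 3 of 4 rose (camera adjusted p = 0.00808; adjusted p = 0.32 with an estimated correlation), miR-130a-3p did not pass (1.33, edgeR adjusted p = 0.25), and all 3 miR-29 members fell (camera adjusted p = 0.0149; adjusted p = 0.32 with an estimated correlation). Of 9 let-7 members 5 fell, and the family did not pass as a set (camera adjusted p = 0.05003, just above the threshold), though it did with RLE factors (0.0445), library totals (0.0454) and without adult VM replicate 1 (0.0168) or 2 (0.0128). Adjusted over the list alone, the counts were 3 higher and 0 lower for miR-130 and miR-301, 0 higher and 3 lower for miR-29 and 0 higher and 5 lower for let-7. Among markers of other cells, miR-126a-3p (1.55) and miR-126a-5p (1.41) were higher in neonatal VM cells, and miR-486a-5p (-1.73) and miR-486b-5p (-1.74) lower. In all, 155 miRNAs passed the edgeR test, 66 higher and 89 lower, against 117 and 49 under library totals (median shift 0.51). MiR-744-5p did not pass with no filter or with filterByExpr (edgeR adjusted p = 0.134 and 0.0528). Without neonatal VM replicate 1 the miR-29 family had adjusted p = 0.0574, and miR-744-5p did not pass without neonatal VM replicate 1 or 2 (edgeR adjusted p = 0.064 and 0.0692). From these separate libraries, 50 miRNAs were higher in neonatal cells of both subsets where 17.4 were expected if the calls were independent, 51 were lower in both where 19.2 were expected, and 3 were called in opposite directions. Both comparisons came from 1 fit with a shared estimate of spread per miRNA, so the calls were not independent and the expected counts are only a rough guide. Across miRNAs, the log2 fold changes in TN and VM cells had Pearson's r = 0.79.

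**Figure D3:**
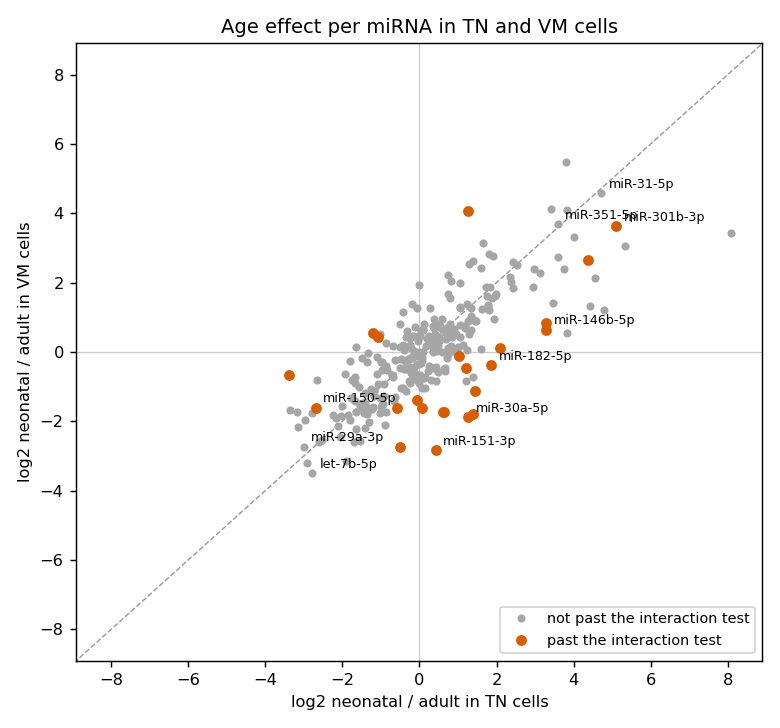
Each point is 1 of 288 miRNAs, with its log2 fold change of neonatal over adult in TN cells on the x axis and in VM cells on the y axis, and the dashed line marks equal effects. Orange points are the 23 miRNAs past the interaction test, among them miR-151-3p and miR-30a-5p.

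Within adult cells, VM was compared with TN in 2 libraries each. MiR-30a-5p was 9.24-fold higher in VM cells, at 13979.7 ± 4148 CPM against 1512 ± 86.3 (mean ± SD, n = 2 each; log2 fold change 3.21, SE 0.23, edgeR adjusted p = 1.37e-06). Mir30a lies within no host gene of its strand (chromosome 1, 23272269 to 23272339). MiR-21a-3p (2.55), miR-21a-5p (2.55), miR-146a-5p (2.52) and miR-340-5p (2.06) rose as well, while miR-181a-2-3p (-3.54), miR-211-5p (-2.82), miR-181a-1-3p (-2.47), miR-181a-5p (-2.44) and miR-181b-5p (-2.29) fell most at that level. Among the 12 T cell activation miRNAs 9 rose and 1 fell (camera adjusted p = 4.55e-04; adjusted p = 0.575 with an estimated correlation), and adjusted over the list alone the counts were 9 higher and 1 lower. Of the 7 tested markers of other cells, 4 were also higher in adult VM cells. MiR-143-3p was at 21.2 ± 6.67 CPM against 6.66 ± 3.3 in adult TN (log2 fold change 1.64, SE 0.44, edgeR adjusted p = 0.0119), and miR-126a-5p at 18.7 ± 5.36 against 4.40 ± 1.65 (log2 fold change 2.05, SE 0.45, edgeR adjusted p = 0.00466). MiR-486a-5p (0.93) and miR-486b-5p (0.94) rose too, while miR-126a-3p, miR-10a-5p and miR-10b-5p did not pass. The untested miR-223-3p, a myeloid miRNA, was at 5.64 and 15.6 CPM in the adult VM libraries and at 2.16 and 1.71 in the adult TN libraries. In all, 112 miRNAs passed the edgeR test, 67 higher and 45 lower. Without adult TN replicates 1 and 2, 51 and 23 passed, and miR-340-5p did not pass without adult TN replicate 2 (edgeR adjusted p = 0.0703).

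Within neonatal cells, 2 VM libraries were compared with 1 TN library. MiR-21a-3p (log2 fold change 1.93, SE 0.31, edgeR adjusted p = 0.00148), miR-340-3p (1.82), miR-21a-5p (1.72), miR-29c-3p (1.21) and miR-222-3p (1.20) were higher in VM cells. MiR-211-5p (log2 fold change -4.00, SE 0.33, edgeR adjusted p = 1.07e-05), miR-181a-2-3p (-3.89), miR-181a-5p (-2.88), miR-181b-5p (-2.86) and miR-181a-1-3p (-2.53) were lower. In the miR-181 family 2 of 4 fell (camera adjusted p = 0.00182; adjusted p = 0.573 with an estimated correlation), and adjusted over the list alone the counts were 0 higher and 2 lower. Of the tested markers of other cells, miR-486a-5p (-1.44) and miR-486b-5p (-1.42) were lower in neonatal VM cells, and the other 5 did not pass. In all, 28 miRNAs passed the edgeR test, 9 higher and 19 lower, against 21 and 14 under library totals (median shift 0.25) and 38 and 14 under upper quartile factors (median shift 0.38). The count was 56 and 77 without adult VM replicates 1 and 2, 16 without adult TN replicate 2 and 17 without neonatal VM replicate 2, where miR-29c-3p did not pass (edgeR adjusted p = 0.0698). Fits without an adult VM library had a median of 570 degrees of freedom against 12 with all libraries, over the 23 miRNAs called in the interaction. Their counts are therefore not like the 28. Of the miRNAs called in adult and in neonatal cells, 6 were higher in VM at both ages where 2.09 were expected, 12 lower where 2.97 were expected, and 4 were called in opposite directions. These calls also shared 1 estimate of spread per miRNA, so they were not independent, as the expected counts assume.

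The interaction asked which miRNAs respond to age differently in VM and TN cells. MiR-151-3p, whose gene lies in an intron of Ptk2 (chromosome 15, 73254815 to 73254882), was at 2869.6 ± 237 CPM in adult VM and 405 ± 42.1 in neonatal VM (mean ± SD, n = 2 each) but 1719 ± 291 in adult TN (n = 2) and 2306 in neonatal TN, an age effect in VM less that in TN of -3.25 on the log2 scale (SE 0.31, edgeR adjusted p = 6.45e-05). MiR-30a-5p was at 1512 ± 86.3 CPM in adult TN and 3648 in neonatal TN but 13979.7 ± 4148 in adult VM and 3776 ± 188 in neonatal VM (-3.16, SE 0.33, edgeR adjusted p = 8.54e-05). MiR-182-5p, which interleukin 2 induces in T helper cells, was at 1101 ± 137 CPM in adult TN, 4577 ± 558 in adult VM, 4009 in neonatal TN and 3532 ± 99.3 in neonatal VM (-2.24, SE 0.30, edgeR adjusted p = 6.30e-04). The next in order of adjusted p were miR-146b-5p (-2.65), miR-151-5p (-2.24), miR-486a-5p (-2.37), miR-486b-5p (-2.36), miR-183-5p (-1.99), miR-30a-3p (-2.56) and miR-146a-5p (-1.66). Mir182 (chromosome 6, 30165918 to 30165992) and Mir183 (chromosome 6, 30169668 to 30169737) lie within no host gene of their strand. MiR-486a-5p and miR-486b-5p overlap at a single locus on opposite strands and could share reads, so they count as uncertain. Of the 12 T cell activation miRNAs, 4 passed, all with a negative interaction, miR-182-5p, miR-146b-5p, miR-183-5p and miR-146a-5p (camera adjusted p = 0.00627; adjusted p = 0.377 with an estimated correlation), and adjusted over the list alone the counts were 1 higher and 7 lower. The stromal marker miR-143-3p also had a negative interaction (-2.46, edgeR adjusted p = 0.0296). In all, 23 miRNAs passed, 5 positive and 18 negative, against 18 and 12 under upper quartile factors (median shift 0.40). Fits without 1 adult VM library had a median of 570 degrees of freedom against 12 with all libraries, so their counts are not like the 23. The count was 86 and 59 without adult VM replicates 1 and 2, 9 and 6 without adult TN replicates 1 and 2, and 13 and 15 without neonatal VM replicates 1 and 2. Without adult TN replicate 1 miR-30a-3p and miR-146a-5p did not pass (edgeR adjusted p = 0.0795 and 0.137), without replicate 2 these (both 0.104), miR-151-5p and miR-183-5p (both 0.0661) did not, and without neonatal VM replicate 1 miR-146a-5p did not (0.0661).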

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

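The tests of GC content, opposite arms, sample label, single-arm noise, adult VM replicate 1, both adult TN replicates, erythroid RNA and the splits with both factors in the model were chosen only after the results were seen; the others were chosen before. Each result here stands out through a tested difference between TN and VM cells in the effect of age, as log2 with the edgeR quasi-likelihood adjusted p after each value. The values were miR-151-3p (-3.25, 6.45e-05), miR-30a-5p (-3.16, 8.54e-05), miR-182-5p (-2.24, 6.30e-04), miR-146b-5p (-2.65, 0.00109), miR-151-5p (-2.24, 0.00109), miR-486a-5p (-2.37, 0.00109) and miR-486b-5p (-2.36, 0.00109). They continued with miR-183-5p (-1.99, 0.00176), miR-30a-3p (-2.56, 0.00176), miR-146a-5p (-1.66, 0.00974), miR-203-3p (-1.31, 0.02), miR-150-5p (1.08, 0.0293), miR-143-3p (-2.46, 0.0296) and miR-125a-5p (1.5, 0.0324). The last were miR-301b-3p (-1.49, 0.0324), miR-301a-3p (-1.72, 0.0406), let-7e-5p (1.77, 0.0438), let-7g-5p (-1.03, 0.0438), miR-98-5p (-1.66, 0.0438) and miR-497a-5p (2.72, 0.0447). These were the calls in a list or named in a comparison, and the other 3 of the 23 were miR-7a-5p (-3.18, 0.0123), miR-877-5p (2.78, 0.0296) and miR-192-5p (-1.16, 0.0353). The T cell activation list had a median of -0.96 (camera adjusted p = 0.00627; adjusted p = 0.377 with an estimated correlation).

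For the interaction of age and subset, the called effects without adult VM replicates 1 and 2 stood at a median of 1.06 and 0.902 times those with all libraries. The required count of calls was met without either adult VM library, but it cannot decide whether 1 of them made the calls. Those fits had a median of 570 degrees of freedom against 12 with all libraries, so the spread was shared almost wholly among miRNAs. Without adult TN replicates 1 and 2, 9 and 6 of the 23 calls remained, which fails the count required of the adult VM libraries, as the median SE rose from 0.36 to 0.42 and 0.41 and the median degrees of freedom fell to 7.18 and 6.42. The median absolute effect went from 2.24 to 1.97 and 2.11, median ratios of 0.945 (95% interval 0.890 to 0.961) and 0.978 (0.964 to 1.02). These intervals resample the 23 called miRNAs and do not cover the spread between libraries. The 23 were called with both adult TN libraries in the fit, so a large drop was unlikely. This test, taken up after that count was seen, therefore cannot decide whether 1 adult TN library made the effects. Most calls rest on both adult TN libraries. Noise of single arms stays open: in the 7 hairpins with a called arm and both arms tested, of which 2 had both arms called, the opposite arms lay in the same direction in 7, by a median of 0.62 (95% interval 0.57 to 2.75) against 1.72 for the called arms, and over 77 hairpins the arms' interactions had r = 0.346 (permutation p = 0.00217). A peculiarity of the lone neonatal TN library cannot be told apart from a difference between the subsets, because that group had 1 library, and biology of age in the subsets stays open too, untested.

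The adult VM replicates lay apart from each other. GC content of the hairpin arm, a stand-in for that of the mature arm, which was not tested, cannot account for it, as the replicate difference had Pearson's r = 0.0187 with it across 287 miRNAs (95% interval -0.0973 to 0.134). Of the 35 miRNAs that differed by over 2-fold, 13 had a tested opposite arm, and the rest were not examined. The opposite arms of these 13 shifted by a median of 0.13 (95% interval 0.06 to 0.22) against 1.40 for the arms themselves. For these 13 the values argue against different transcription of the loci as the whole cause. The 13 were picked for large differences and their opposite arms were not, which can make the latter look smaller, and the interval does not cover this. An adult TN library under an adult VM label is excluded, because over the 28 miRNAs called by subset in neonatal cells replicates 1 and 2 lay 0.85 (95% interval 0.57 to 2.05) and 1.11 (0.55 to 1.81) to the VM side of the adult TN mean, and an adult TN library at most 0.09 (0.01 to 0.17), although replicate 1 correlated with replicate 2 (r = 0.981) by only 0.0144 more than with adult TN replicate 1, under the 0.02 first set. Other wrong labels were not tested, nor was a biological explanation.

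For the difference between neonatal and adult cells, 34 of 35 splits of the 7 libraries could be fitted. Of these 1 gave as many calls, the real one with 155, and the highest other gave 1. For VM against TN cells the real split gave 71 calls, 1 of 34, and another at most 2. The real count was 35 without adult VM replicate 1, 25 and 18 without adult TN replicates 1 and 2, and 47 and 20 without neonatal VM replicates 1 and 2. The other splits left a real difference in the residual, which lowers their counts. They therefore cannot decide whether chance in how the libraries fell into groups made the calls. With age and subset both in the model, which has 1 more term than the real fits, 33 splits gave at most 23 calls, for the split that equals the interaction, and otherwise at most 15. The splits with 15 calls set adult VM replicate 2 apart, given age and subset. Splits other than the interaction left it at least partly in the residual, which can lower their counts, so they cannot decide the question either. Counts with 1 library left out come from fewer libraries and cannot be set against these. Chance between animals is not excluded, since the replicates may share animals. When the 5 most abundant miRNAs were left out of the library sizes, 149 of the 155 age calls remained in the same direction. Both fits used TMM factors, and their log2 fold changes differed by a median of 0.082. The test therefore cannot decide whether a few abundant miRNAs taking the counts made the age calls. Under library totals alone 129 of the 155 remained in the same direction, with a median shift of 0.45 and with 119 miRNAs higher and 53 lower. Erythroid RNA in the neonatal sorts would be depleted by enrichment with beads against CD8 and by the sort. By 1 marker the values argue against it as the cause, since miR-451a gained 3.70 CPM against a median gain of 45.1 CPM among the miRNAs that rose. RNA of stromal, myeloid or progenitor cells was not tested and stays open for the age calls. Neonatal against adult means were 47.6 and 13.9 CPM for miR-143-3p and 49.7 and 11.5 CPM for miR-126a-5p. MiR-10a-5p went the other way, at 48.1 and 122.8 CPM. An age difference in the cells remains a hypothesis for the age calls, found and tested on the same data.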

How the results depend on the processing

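The fits on the largest precursor value of each mature name and with a hairpin GC offset were chosen after seeing the data; the rest were chosen before. No value changed direction while called. Under the 100 CPM filter, which left 153 miRNAs, the calls were 79 for age over both subsets, 41 for subset over both ages, 69 for age in TN and 93 for age in VM, where fewer miRNAs were tested. For the subset in neonatal cells the calls were 52 under upper quartile factors, 53 with no filter (878 tested), 49 with filterByExpr (433 tested) and 80 with only the libraries compared, and the cause was not tested. The interaction had 14 calls with library sizes without the 5 most abundant miRNAs, 43 with no filter, 43 with filterByExpr, 41 with DESeq2 and 15 with limma voom, and the cause was not tested. Of the 77 list tests 13 passed, 0 of camera's tests with an estimated correlation (3 at an unadjusted p under 0.05) and 36 with fry, which asks a different question. Without the neonatal TN library the averages rest on VM cells alone for age (152 calls) and on adult cells alone for subset (111 calls). In the cell means model, fits without an adult VM library gave the highest count of each comparison in the ranges that follow. Those fits had a median of 570 degrees of freedom against 12 with all libraries, over the 23 interaction calls, so these highest counts are not like the main ones. Leaving out each library in turn, except the neonatal TN library where a comparison needs it (age in TN, subset in neonatal cells, the interaction and the count of list tests), gave 115 to 158 calls for age over both subsets, 18 to 111 for subset over both ages, 83 to 179 for age in TN, 106 to 171 for age in VM, 23 to 142 for subset in adult cells, 16 to 77 for subset in neonatal cells, 6 to 86 for the interaction and 10 to 21 for the list tests, and the lone library of a group was assumed to vary like the others. The highest list count, 21, came without adult VM replicate 2, where lists that had not passed did, by subset in adult cells miR-130 and miR-301 (0.0289) and miR-181 (0.00915), in the interaction miR-130 and miR-301 (0.0141) and miR-15/16 (0.0256), for age in TN the resting list (0.0321) and for age in VM miR-181 (0.0128). The miR-15/16 interaction also passed without adult TN replicate 2 (0.0339) and neonatal VM replicate 1 (0.0438), and the resting list for age in TN without adult VM replicate 1 (0.0478). The named miRNAs kept their direction and call in every setting that tested them in 24 of 24 cases for age, 12 of 24 for subset, 10 of 10 for age in TN, 9 of 10 each for age in VM, subset in adult and subset in neonatal cells, and 6 of 10 for the interaction. Not tested were miR-669a-3p on the largest precursor value and under the 100 CPM filter, miR-99b-5p under that filter and miR-31-5p for age in TN with only the libraries compared. The T cell activation list by subset had adjusted p = 0.064 with fry and 0.055 with library totals. Replicate numbers are shared between groups without a stated pairing, and deviations of like-numbered libraries had r = 0.0165, 0.138 and -0.16; with the number as a block, 42 miRNAs were called by subset and 12 list tests passed, and the activation list by subset did not pass (adjusted p = 0.066). Library totals of 1577031 to 3278451 counts put the 10 CPM filter at 15.8 to 32.8 counts.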

Other observations

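Genomic clusters were grouped, after the values were seen, as precursors within 10 kb of each other. Of 9 clusters with at least 5 tested arms, 2 passed as sets with age and 7 did not (camera adjusted p from 0.0553 to 0.951), and 2 passed by subset and 7 did not (0.799 to 0.964). At 53047997 to 53054349 on chromosome X (GRCm38), all 5 tested arms of miR-322, miR-351 and miR-450 rose in neonatal cells, with a median log2 fold change of 2.06 (camera adjusted p = 9.81e-04; adjusted p = 0.169 with an estimated correlation). The same 5 arms fell in VM cells, with a median of -1.17 (camera adjusted p = 0.0186; adjusted p = 0.379 with an estimated correlation). At 10466944 to 10514971 on chromosome 2, in introns of Sfmbt2, 17 of 21 arms of the miR-466, miR-467 and miR-669 families were lower in neonatal cells (median -1.48; camera adjusted p = 6.10e-05; adjusted p = 0.46 with an estimated correlation), and 13 were lower in VM cells (median -1.28; camera adjusted p = 2.75e-06; adjusted p = 0.702 with an estimated correlation). These near-identical copies could have been given each other's reads, which was not tested, so their separate values are uncertain.

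The arms were compared after the values were seen. Across 77 hairpins with both arms tested, the log2 fold changes of the arms had Pearson's r = 0.78 with age and 0.73 by subset, across hairpins that are not independent replicates. With age both arms were called in 29 hairpins, in the same direction in 29, but in TN cells alone the direction was the same in 19 of 21, and in VM cells alone in 29 of 30. By subset both were called in 9, in the same direction in 9. Some hairpins differed between arms, picked after their values were seen: miR-150-5p fell with age (-2.01) while miR-150-3p was at 0.22 (edgeR adjusted p = 0.531), and miR-139-5p fell (-1.90) while miR-139-3p was at 0.38 (edgeR adjusted p = 0.191).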
